A study of Mus musculus with 12 samples.

How the data were processed

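Gene expression was measured by RNA sequencing in mouse fibroblasts. The labels describe 6 groups of 2 libraries each, 12 libraries in all: mock, HT-DNA, hpRNA, cGAMP, G3-YSD and HSV. The source name is L929 cells, an established mouse fibroblast line, for cGAMP, G3-YSD and HSV. For mock, HT-DNA and hpRNA it is mouse fibroblast cell line, which does not name L929. Abbreviations are given as the labels write them. RNA was collected 6 hours after transfection, and per the labels' protocols polyA-selected RNA was read in pairs of 150 bases by Illumina sequencing. Transfections were made in duplicate per the labels, which do not say more about how the 2 libraries of a label were made. The p-values therefore measure the spread between libraries of one label, part of which may be technical. In the fit of all 12 libraries that spread is 1 estimate per gene over all 6 labels. Each comparison thus also carries the spread of labels outside it, such as the wide G3-YSD and HSV pairs. The 1 or 2 that ends each sample title was read as a replicate number. For HSV the same digits could also name virus types 1 and 2, which the labels do not settle, as both samples are described as HSV transfection. In that case HSV would be 2 groups of 1 library, and its means, SDs and calls would not describe one group.

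The deposited files hold raw counts per Ensembl gene, 1 file per library. HISAT2, HTSeq and the build mm10 are named in the submitters' processing notes, without versions. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping, antisense and near-identical genes may be shared between them. Each file lists 54532 genes, of which 54409 matched a gene of GENCODE release M21, which uses the same assembly. Symbols and positions come from that release. Total counts ranged from 12650790 to 18912400 per library.

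Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with edgeR's default filter, which left 16840 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 term per label was fitted to all 12 libraries, with 6 residual degrees of freedom and a biological coefficient of variation of 0.397. Each of 9 comparisons was tested in that fit, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Levels are CPM, counts scaled by library total, on the TMM scale, computed here from the deposited counts, and errors of group means are SDs over 2 libraries. Errors of log2 fold changes are standard errors from the quasi-likelihood test.

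The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. For each stimulus against mock, the rule takes the 8 called genes with the largest change in each direction whose libraries do not overlap between the labels and whose higher group mean is at least 5 CPM, leaving out predicted genes and pseudogenes by their symbols. To these it adds up to 4 called members of each list and 15 genes reported whatever their result. Between 2 stimuli it takes 6 genes in each direction and up to 3 members per list. The 19 lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over 171 tests.

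Pairs of libraries were compared by a noise ratio, the median over genes with at least 100 counts in the pair of the squared difference in counts over its expectation from counting noise, scaled so that 1 is counting noise alone. The same ratio was computed after thinning each library at random to the lowest total, and for each library split at random into 2 parts of equal size. Fold changes of 2 stimuli against the shared mock libraries were set beside 20 simulations of unchanged groups, and computed again with each stimulus against another one of the 2 mock libraries.

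Genes silent in the 8 libraries labelled mock, HT-DNA, hpRNA and cGAMP (at most 2 counts in all 8) were sorted by their position to expressed genes (mean of at least 5 CPM in the same 8). The 3' and 5' sides refer to expressed genes of the same strand, with none on the other side within the outer distance. Far genes had no expressed gene of either strand nearby. The 2663 silent genes that overlap an expressed gene were left out. A silent gene counted as detected with at least 5 counts at equal depth, and shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

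The test was tested on simulated counts for HT-DNA against mock over 16073 genes. With the spread of the real libraries it recovered 1 of 68 genes changed by 1 on the log2 scale, 43 of 66 changed by 2 and 64 of 66 changed by 4, with 8 false calls. The changed genes were drawn at random from those of at least 5 CPM. This recovery does not describe genes with a wide spread, such as Ifit1, with a standard error of 2.55 in HT-DNA against mock. For such genes even a change of 4 could go uncalled. Alternatives tried were RLE and upper quartile scaling, no filter on low counts, DESeq2 1.42.0, a fit of only the 4 libraries compared, the replicate number as a block (over all 12 libraries, and within 4 or 8 of them), and leaving out each library in turn. In the last, the remaining library of that label is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9.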

Results

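Transcripts of mouse fibroblasts were counted in 12 libraries, 2 under each of the labels mock, HT-DNA, hpRNA, cGAMP, G3-YSD and HSV, to compare the response to several stimulators of cells at 6 hours. The source name gives L929 for cGAMP, G3-YSD and HSV only. cGAMP is the second messenger made by the DNA sensor cGAS. Total counts per library lay between 12650790 and 18912400. Between 21635 and 22550 genes were detected in the 8 libraries labelled mock, HT-DNA, hpRNA and cGAMP, against 26496 in G3-YSD 1, 26241 in HSV 1, 23997 in G3-YSD 2 and 23909 in HSV 2.

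The labels and the counts disagreed about which libraries belong together. Each of the 12 libraries was closest to a library with another label and the same replicate number, in 6 reciprocal pairs. Mock 1 paired with hpRNA 1 at a noise ratio of 1.84 and mock 2 with hpRNA 2 at 1.67. HT-DNA 1 paired with cGAMP 1 at 1.55 and HT-DNA 2 with cGAMP 2 at 1.74. G3-YSD 1 paired with HSV 1 at 2.08 and G3-YSD 2 with HSV 2 at 1.42. The 2 libraries of one label differed more, with ratios of 8.51 for mock, 3.32 for HT-DNA, 8.25 for hpRNA, 3.97 for cGAMP, 85.4 for G3-YSD and 78.9 for HSV. All 12 libraries kept a closest library of another label at equal depth and by the correlation of log2 CPM. Groups below are therefore named as the libraries labelled so, and no library was moved to another group. Mock, HT-DNA and hpRNA carry another wording of the cell source than cGAMP, G3-YSD and HSV. In comparisons of cGAMP, G3-YSD or HSV with mock, the design cannot separate a batch of these libraries from the treatment. Libraries cGAMP 1 and cGAMP 2 lay at only 1.55 and 1.74 from HT-DNA 1 and HT-DNA 2, across the 2 wordings. If the labels hold, this argues against a large batch that follows the wording in all its libraries. A batch of the G3-YSD and HSV libraries alone stays open.

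**Figure D1:**
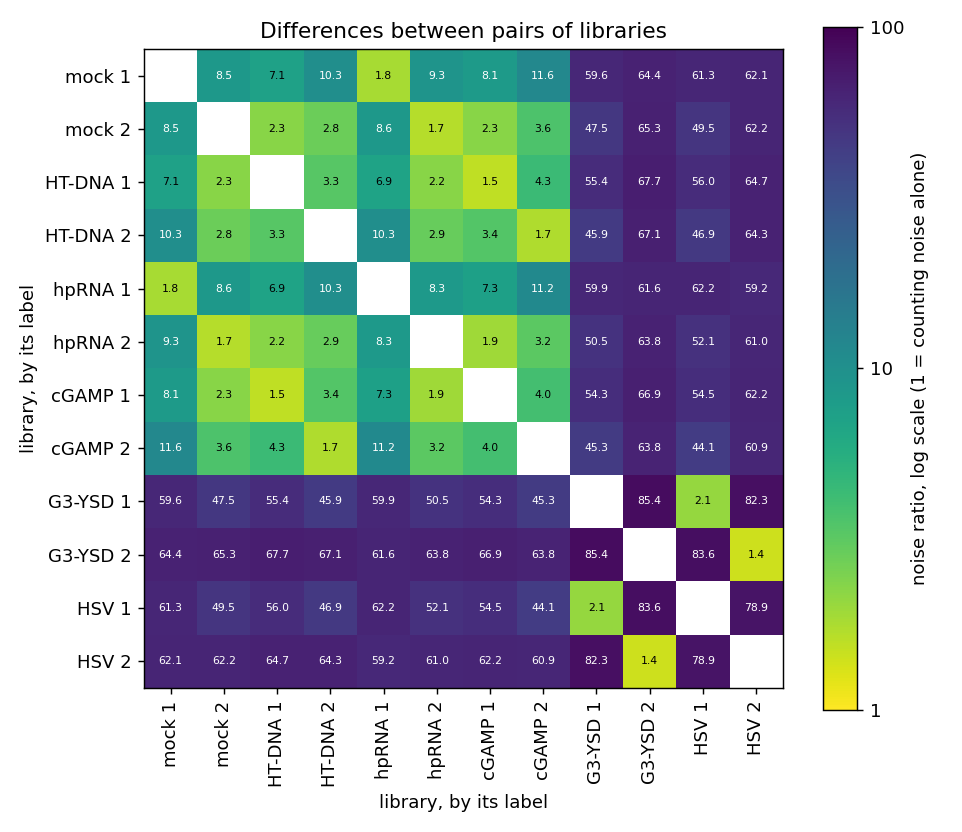
Noise ratio between each 2 of the 12 libraries, on a log color scale on which 1 is counting noise alone, with libraries in rows and columns by their label. The lowest ratio in each row, between 1.42 and 2.08, joins libraries of different labels.

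Interferon-stimulated genes differed widely between libraries of the same label. Ifit1, an interferon-induced antiviral gene (chromosome 19, 34640871 to 34650009, mm10), stood at 2.10 CPM in mock 1 and 486 CPM in mock 2, and at 2.28 CPM in hpRNA 1 and 441 CPM in hpRNA 2. Its level was 153 CPM in HT-DNA 1, 661 CPM in HT-DNA 2, 178 CPM in cGAMP 1 and 672 CPM in cGAMP 2. In G3-YSD 1 and HSV 1 Ifit1 reached 1805 and 1696 CPM, against 65.7 and 54.9 CPM in G3-YSD 2 and HSV 2. Ifnb1, which encodes interferon beta, had 0 counts in mock 1 and hpRNA 1, 30 in mock 2 and 11 in hpRNA 2. It had 13 and 183 in HT-DNA 1 and 2, 7 and 142 in cGAMP, 450 and 56 in G3-YSD, and 390 and 50 in HSV. Rsad2, Isg15, Irf7 and Cxcl10 were likewise higher in mock 2 than in mock 1, at 744 against 3.41 CPM for Rsad2. Of the 75 interferon-stimulated genes tested, 0 were called in each of the 9 comparisons by edgeR's quasi-likelihood test in the fit of all 12 libraries, and 0 were called higher by DESeq2, with 0 at an unadjusted p under 0.05. That fit does not pair libraries by number, and fits that do are given below. With standard errors such as 2.55 for Ifit1 in HT-DNA against mock, a lack of calls does not show a lack of response. Their summed level was 1531 and 11704 CPM in mock 1 and 2, 5283 and 16019 CPM in HT-DNA, 1542 and 10650 CPM in hpRNA, and 5739 and 16693 CPM in cGAMP. In G3-YSD it was 36290 and 1884 CPM and in HSV 36258 and 1858 CPM, so hpRNA 2, G3-YSD 2 and HSV 2 lay below mock 2.

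**Figure D2:**
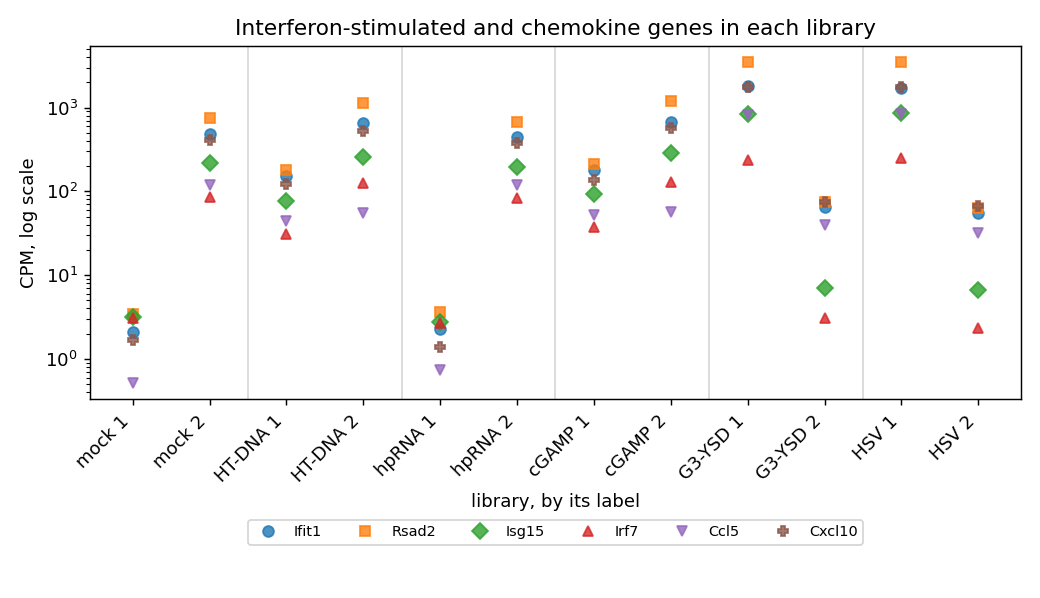
CPM of 6 interferon-stimulated and chemokine genes in each of the 12 libraries, on a log axis, 1 point per gene and library. Ifit1 ranges from 2.10 CPM in mock 1 to 1805 CPM in G3-YSD 1, and the 2 libraries of mock lie at 2.10 and 486 CPM.

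The libraries labelled HT-DNA were compared with those labelled mock to ask what HT-DNA transfection changes. Ifit1 had a log2 fold change of 0.74 with a standard error of 2.55, Ifnb1 of 2.70 with 2.10, and Nfkbia, the NF-kB inhibitor that NF-kB itself induces, of 0.16 with 0.18. edgeR called 0 of 16840 genes, 62 genes had an unadjusted p under 0.05 where chance gives 842, and DESeq2 called 1. That gene, Frmd3, was looked up after its result was seen, and its level was at most 0.122 CPM in the 4 libraries compared. The spread behind these p-values includes the G3-YSD and HSV pairs. An edgeR fit without these 2 labels, chosen after seeing the data, called 0, with 288 of 14543 genes at an unadjusted p under 0.05. The interferon-stimulated gene list was called higher with a preset correlation at an adjusted p of 1.69e-11, and was not with an estimated one, at an adjusted p = 0.917. With the replicate number as a block within the 8 libraries labelled mock, HT-DNA, hpRNA and cGAMP, chosen after seeing the data, edgeR called 14 genes higher, 4 of them interferon-stimulated: Daxx at 0.94, Slfn9 at 0.72, Tlr3 at 1.45 and Ifit1bl1 at 3.08 on the log2 scale. These 4 were named after their results were seen, and the labels do not say what a shared number marks.

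In the comparison of hpRNA with mock, Ifit1 had a log2 fold change of -0.14 with a standard error of 2.54, and Nfkbia of 0.04 with 0.18. The edgeR count was 0, with 58 genes at an unadjusted p under 0.05, and DESeq2 called 1, Sult1c2, named after its result was seen and at most 0.183 CPM in these 4 libraries. A fit of the 4 libraries with the replicate number as a block, chosen after seeing the data, called 182 genes, 126 higher and 56 lower. Among these were 14 interferon-stimulated genes, all lower, by 0.13 to 0.33 on the log2 scale. Of these, Ifit1 and Rsad2 were lower in hpRNA 2 than in mock 2, but not in hpRNA 1, at 2.28 and 3.65 CPM against 2.10 and 3.41 CPM in mock 1. The summed list was likewise 1542 CPM in hpRNA 1 and 1531 CPM in mock 1, so a fall in both pairs was not shown. The block within the 8 libraries called 0, with 355 at an unadjusted p under 0.05. Cytosolic ribosomal protein genes, 76 in all, were called higher as a list with the preset correlation, with a median log2 fold change of 0.08, and had an adjusted p = 0.917 with an estimated correlation.

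For cGAMP against mock, Ifit1 had a log2 fold change of 0.80 with a standard error of 2.55, Ifnb1 of 2.39 with 2.09 and Isg15 of 0.79 with 2.59. No gene was called by edgeR (99 had an unadjusted p under 0.05) or by DESeq2, which gave 0. HT-DNA against hpRNA also gave 0 calls with either tool, with 77 genes at an unadjusted p under 0.05, and Ifnb1 had a log2 fold change of 4.23 with a standard error of 2.34. In both comparisons the interferon-stimulated gene list passed with the preset correlation and had an adjusted p = 0.917 with an estimated one. With the block within the 8 libraries, 23 genes were called for cGAMP against mock, 22 higher and 1 lower, and 25 for HT-DNA against hpRNA, 24 higher and 1 lower. Among them were 4 and 5 interferon-stimulated genes, all higher and named after their results were seen: Daxx, Slfn9, Tlr3 and Ifit1bl1 in both, and Slfn8 in the second.

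In the libraries labelled G3-YSD, some NF-kB feedback and immediate-early genes were higher than in mock, and some genes of hypoxia, glycolysis and cholesterol synthesis were lower. A batch that sets the G3-YSD libraries apart from mock cannot be told apart from the treatment here. Nfkbia (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647) rose from 103 ± 16.5 to 318 ± 27.3 CPM (SD, n = 2 each), a log2 fold change of 1.63 with a standard error of 0.19 and an edgeR adjusted p of 0.00835, higher in 2 of 2 libraries. Fosb, an immediate-early transcription factor, rose by 4.12 on the log2 scale, Ccn1 by 2.92 and Egr2 by 2.42. Eno2, a glycolytic enolase, fell from 104 ± 20.4 to 18.5 ± 6.97 CPM (n = 2 each). Vegfa, Bnip3 and Adm, which hypoxia induces, had log2 fold changes of -1.64, -1.63 and -2.31.

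Of the lists, 5 of 31 immediate-early genes rose and 2 fell in G3-YSD against mock, and 2 of 28 NF-kB genes, Nfkbia and Sqstm1, rose while Tnfaip2 fell. Adjusted over the list alone, 8 immediate-early genes were higher and 2 lower, and 10 NF-kB genes were higher and 2 lower. Cholesterol synthesis had 5 of 24 members lower, among them Sqle at -1.10, the squalene epoxidase, and Fdps at -1.60, and 6 adjusted over the list alone. Hypoxia and glycolysis had 5 of 30 members lower and cell cycle 4 of 44, among them Aurkb at -1.02 and Ccnb1 at -0.59, and adjusted over the list alone 7 and 5. The stress response list had 3 of 33 lower (Cebpb, Slc7a11 and Ddit4), heat shock 2 of 19 (Hspb8 and Hspa1b), p53 targets 1 of 25 (Gdf15) and nucleic acid sensing 1 of 32 (Ticam1). Histones had 2 of 32 higher (Hist1h4k and Hist2h4), fibroblast matrix 2 of 31 (Fbn1 and Timp1), chemokines and cytokines 1 of 31 (Ccl9), and mitochondrial transcripts 1 of 25 (mt-Rnr2). Some lists as a whole differed between the 2 G3-YSD libraries. Stress response summed to 17041 and 29942 CPM in G3-YSD 1 and 2, against 21789 and 21686 CPM in mock 1 and 2. Fibroblast matrix summed to 6025 and 10968 CPM against 8126 and 7794 CPM, and cell cycle to 5473 and 6792 CPM against 6949 and 6671 CPM. Adjusted over the list alone, 3 histones and 4 matrix genes were higher, 0 p53 targets were called, and 1 nucleic acid sensing gene was higher and 1 lower. Among 8 interferon genes Ifna13 was called, at least 10.3-fold higher over a floor of 3 counts per mock library and at least 3.48-fold without G3-YSD 1, and it shares reads with near-identical family members. Reads of histones, Hspa1b, mt-Rnr2, Fdps and Ccnb1 may likewise be shared with near-identical sequences. RNA was polyA-selected, and how that selection bears on the counts of replication-dependent histones was not tested. No member was called of the guanylate-binding protein list (23 tested), antigen presentation (25), ribosomal proteins (76) or markers of other cell types (19). The last list had a median log2 fold change of 1.04 and a preset adjusted p of 0.0145, against an adjusted p = 0.68 with an estimated correlation. Of these lists 14 passed camera with the preset correlation and 0 with an estimated one, where the lowest was an adjusted p = 0.0753, for histones, and cholesterol synthesis had an adjusted p = 0.576. The median, mean and test differed in sign for nucleic acid sensing (0.19, 0.41 and down), p53 targets (0.25, 0.15 and down) and heat shock (-0.09, 0.19 and down), which did not pass. In G3-YSD 2 mitochondrial genes took 3.64% of counts, against 2.03% in G3-YSD 1.

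The genes with the largest higher values were under 1 CPM in mock, and some were uneven between the G3-YSD libraries. Slc17a8, a vesicular glutamate transporter, had 16.3 CPM in G3-YSD 1 and 3.54 CPM in G3-YSD 2, and Cfap53 had 3.66 and 13.7 CPM, while Syt14 had 4.49 and 6.15 CPM. Igf1, a growth factor, had a log2 fold change of 4.30 with a standard error of 0.58. Cfap53 starts 0.358 kb past the end of Mbd1, an expressed gene of the same strand. For Slc17a8, Syt14 and Igf1 the nearest such gene ends 17.5, 55.3 and 1020 kb away. Whether reads of single genes run on from a neighbour was not tested. Gpr35, Efna4, Chst1 and Hdhd3 were among those with the largest lower values, between -2.41 and -2.85 on the log2 scale. In all, edgeR called 869 genes, 302 higher and 567 lower, against a median log2 fold change of all genes of 0.107. Upper quartile scaling called 678, of which 364 were higher and 314 lower, and DESeq2 called 2043, 962 higher and 1081 lower. The count was 1894 without the filter on low counts, with the balance turned to 1160 higher and 734 lower, 0 without mock 1, 0 without mock 2, 77 without G3-YSD 2 and 0 in a fit of these 4 libraries alone. Of the 94 called values of named genes in G3-YSD and HSV against mock, 0 kept their call without mock 1 or without mock 2.

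**Figure D3:**
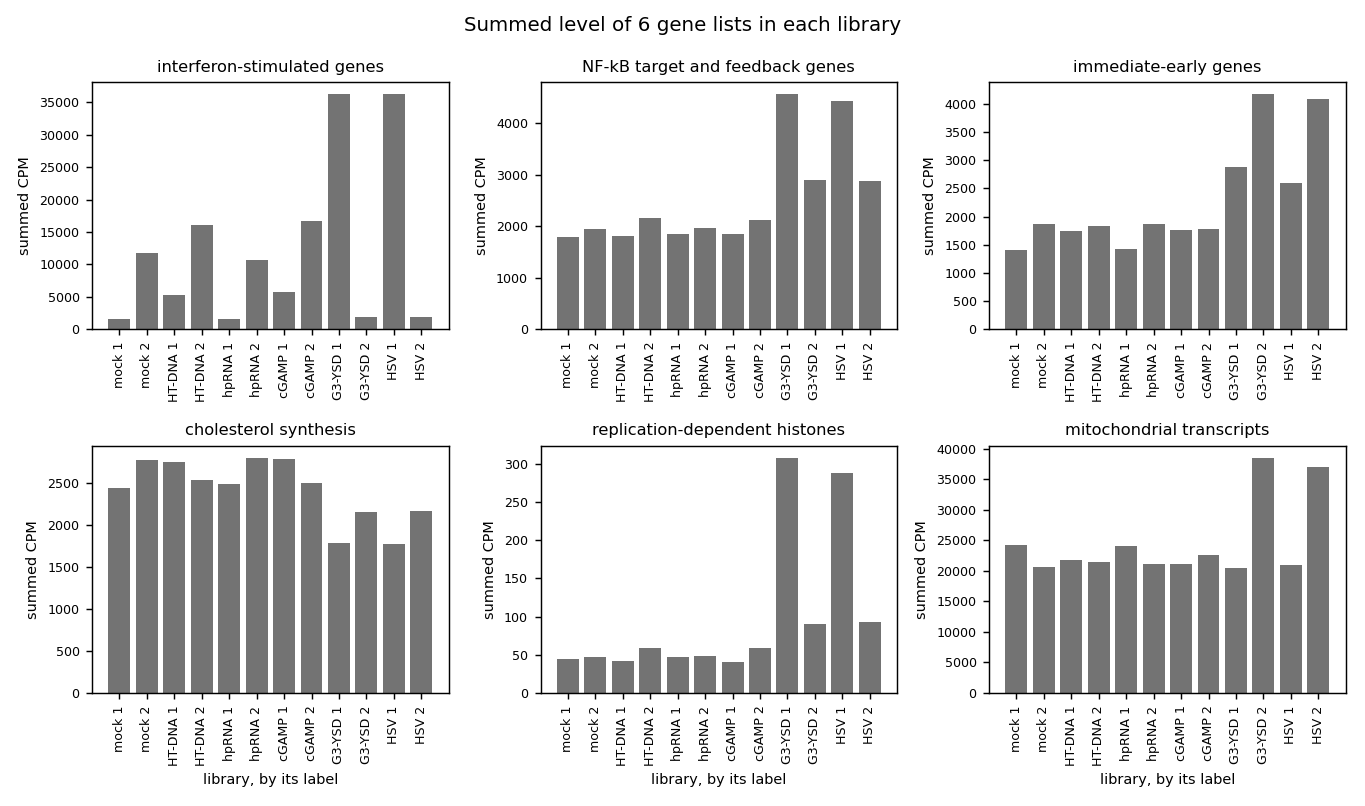
Summed CPM of the tested members of 6 gene lists in each of the 12 libraries, as bars from 0 on linear axes that differ between panels. Histones sum to 308 CPM in G3-YSD 1 and 90.3 CPM in G3-YSD 2, and interferon-stimulated genes to 1531 CPM in mock 1 and 11704 CPM in mock 2.

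The libraries labelled HSV gave values against mock close to those of G3-YSD. The same limit of a batch applies to the HSV libraries. Nfkbia rose by 1.56 on the log2 scale with a standard error of 0.19, with an edgeR adjusted p of 0.00995, Ccn1 by 2.87 and Igf1 by 4.34. Eno2 fell by 2.74, Gpr35 by 2.83 and Vegfa by 1.65. Immediate-early genes had 4 of 31 members higher and 2 lower, cholesterol synthesis 5 of 24 lower, hypoxia and glycolysis 5 of 30 lower and cell cycle 3 of 44 lower. Adjusted over the list alone, 6 immediate-early genes were higher and 2 lower, and 7 cholesterol synthesis, 6 hypoxia and glycolysis and 6 cell cycle genes were lower. Ier3, an immediate-early gene, was lower at -1.97. Of 28 NF-kB genes Nfkbia and Sqstm1 rose and Tnfaip2 fell by 0.86, and adjusted over the list alone 10 were higher and 2 lower. Of 32 nucleic acid sensing genes Rnaseh2b, a subunit of ribonuclease H2, rose by 0.85 and Ticam1 fell by 1.61, and adjusted over the list alone 1 was higher and 2 lower. Stress response had 2 of 33 lower, heat shock 2 of 19 and p53 targets 1 of 25, while histones had 2 of 32 higher, fibroblast matrix 2 of 31, chemokines and cytokines 1 of 31 and mitochondrial transcripts 1 of 25. The p53 targets had 2 higher and 2 lower when adjusted over the list alone. Stress response then had 3 lower and fibroblast matrix 4 higher. Summed levels differed between HSV 1 and HSV 2 as between the G3-YSD libraries. They were 16885 and 29635 CPM for stress response, 5745 and 10832 CPM for fibroblast matrix, and 5504 and 6716 CPM for cell cycle. Ifna13 was at least 13.3-fold higher over the same floor, and at least 6.54-fold without HSV 1. edgeR called 876 genes, 291 higher and 585 lower, upper quartile scaling 651 (347 higher and 304 lower) and DESeq2 2119 (963 higher and 1156 lower). The median log2 fold change of all genes was 0.105. Without the filter on low counts 1892 were called, 1150 higher and 742 lower, without mock 1 or mock 2 the count was 0, without HSV 2 it was 130, and with these 4 libraries alone it was 0. Camera called 14 lists with the preset correlation and 0 with an estimated one, where histones had the lowest value, an adjusted p = 0.0753.

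G3-YSD and HSV against mock shared 252 genes called higher and 514 called lower, with 0 in opposite directions. Independent lists of those sizes would share 5.22 and 19.7 genes, which leaves the shared mock libraries out of account. Simulated unchanged groups shared 0, but they held no changed genes, so hardly any calls could be shared. Neither number is therefore a full reference for the overlap. Across genes, which are not independent replicates, the fold changes correlated at r = 0.98 against a simulated 0.49, with a covariance of 2.61 against 0.33. The simulation treats the 2 labels as independent, while deviations of same-numbered G3-YSD and HSV libraries correlated at 0.93 across genes. With the mock libraries split, 1 for each stimulus, a setting chosen after seeing the data, r was 0.82 both ways against a simulated 0.03, with covariances of 2.93 and 2.92 against 0.04, but 0 calls were left to share. Part of the overlap may come from the shared controls, and part of either value from that pairing. The other 9 pairs of stimuli could share no calls, since HT-DNA, hpRNA and cGAMP had 0 against mock. For these pairs the correlation of HT-DNA with cGAMP was 0.62 against a simulated 0.50, with a covariance of 0.23 against 0.33, and the other 8 correlations, from 0.13 to 0.47, lay below their simulated 0.49 to 0.50. Of these 8, the covariances of HT-DNA and cGAMP with G3-YSD and HSV, from 0.36 to 0.37, lay above a simulated 0.33. The simulation gives every label the spread of all 12 libraries, which includes the wide G3-YSD and HSV pairs. Its values are therefore no close reference for mock, HT-DNA, hpRNA and cGAMP.

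HSV against G3-YSD gave 0 calls with edgeR and 33 genes at an unadjusted p under 0.05, and DESeq2 called 1, Rps12-ps9, a pseudogene named after its result was seen. Nfkbia differed by -0.06 on the log2 scale with a standard error of 0.18 and Ifit1 by -0.10 with 2.53. A fit of these 4 libraries with the replicate number as a block, chosen after seeing the data, called 13 genes, 8 higher and 5 lower.

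Against cGAMP, some immediate-early and NF-kB feedback genes were higher in the libraries labelled G3-YSD and HSV, and some cholesterol synthesis genes were lower. Fosb had a log2 fold change of -3.48 in cGAMP against G3-YSD and 3.36 in HSV against cGAMP. Nfkbia differed by -1.50 and 1.44, and Cyld, a deubiquitinase that restrains NF-kB, by -1.20 and 1.19. Hspb8, a small heat shock protein gene, differed by 1.64 and -1.64, and Sqle by 1.10 and -1.09. Genes of further lists were called in either direction. Among them were Adm of hypoxia and glycolysis at 2.44 and -2.50, Aurkb of cell cycle at 1.00 and -1.02, and Hist1h4k of histones at -2.29 and 2.47. Immediate-early genes had 2 higher and 5 lower of 31 in cGAMP against G3-YSD and 4 higher and 2 lower in HSV against cGAMP, with an adjusted p = 0.68 with an estimated correlation in each. NF-kB genes had 1 higher and 3 lower of 28 in the first and 3 higher and 1 lower in the second, with an adjusted p = 0.91, and Tnfaip2 went the other way at 0.64 and -0.77. Adjusted over the list alone, immediate-early counts were 2 higher and 10 lower, then 7 higher and 2 lower, and NF-kB counts 2 higher and 10 lower, then 10 higher and 2 lower. Cholesterol synthesis had 6 of 24 members called in each comparison, 9 adjusted over the list alone, with an adjusted p = 0.576 with an estimated correlation. edgeR called 842 genes in cGAMP against G3-YSD, 530 higher and 312 lower, and 856 in HSV against cGAMP, 299 higher and 557 lower. Upper quartile scaling gave 295 higher and 375 lower in the first and 360 higher and 297 lower in the second, and DESeq2 gave 1050 and 902 in the first and 845 and 1082 in the second. The first count was 0 without cGAMP 1, 0 without cGAMP 2 and 206 without G3-YSD 2. The second was 0 without either cGAMP library and 146 without HSV 2, and of the 80 called values of named genes 0 kept their call without either. Without the filter the counts were 1650 and 1633, with the balance turned to 681 higher and 969 lower in the first and 954 higher and 679 lower in the second. With only the 4 libraries compared both were 0. These comparisons lie within the samples whose labels share one wording of the cell source, while mock, HT-DNA and hpRNA carry another. A shared wording does not show a shared batch.

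Genes silent in the 8 libraries labelled mock, HT-DNA, hpRNA and cGAMP were sorted by their position to expressed genes, and their detection was counted in the G3-YSD and HSV libraries. In G3-YSD 2, 27 of 338 silent genes within 10 kb on the 3' side of an expressed gene were detected, 7.99% (exact Clopper-Pearson 95% interval 5.33 to 11.4), and in HSV 2 32 of 338, 9.47% (6.57 to 13.1). On the 5' side the shares were 1.17% and 0.97% of 514 genes, and over 100 kb away 0.218% and 0.196% of 17891. In G3-YSD 1 and HSV 1 the shares were 1.18% and 1.78% on the 3' side, 1.95% and 2.53% on the 5' side, and 1.48% and 1.33% far away.

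**Figure D4:**
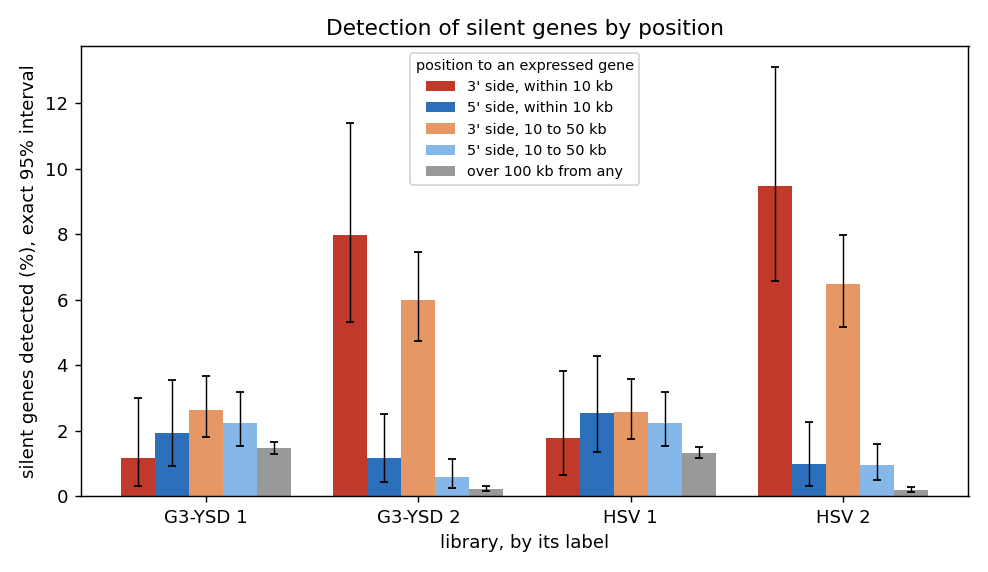
Percent of silent genes detected, by position to expressed genes and library, with exact 95% intervals. The 3' and 5' sides refer to expressed genes of the same strand. The 3' side within 10 kb lies at 7.99% in G3-YSD 2 and 9.47% in HSV 2, against 1.18% in G3-YSD 1 and 1.78% in HSV 1.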

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

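The tests of how the libraries pair were chosen only after the result was seen, and the comparisons between stimuli were planned. Among the stimuli, cGAMP against G3-YSD gave 842 called genes and HSV against cGAMP 856, each a tested difference between libraries labelled so. Both counts were 0 in a fit of only the 4 libraries compared.

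Each library was closest to a library of another label. One library deposited under 2 labels is argued against, since the lowest noise ratio of the closest pairs was 1.42 and libraries split at random into parts of equal size gave at most 1.03. Mislabelled samples stay open: that 12 of the 12 libraries had their closest partner under another label is the observation itself. Ifit1 followed the same pairs, at 2.10 and 2.28 CPM in mock 1 and hpRNA 1 against 486 and 441 CPM in mock 2 and hpRNA 2. Detection of silent genes within 10 kb on the 3' side of expressed genes followed the pairs too. It was 1.18% and 1.78% in G3-YSD 1 and HSV 1, against 7.99% and 9.47% in G3-YSD 2 and HSV 2. Such levels and shares come from the same counts, so they cannot tell crossed labels from a batch. No other value examined here decides it. A separate batch or day for each of the 6 closest pairs cannot be told apart from them, because 0 of the 6 pairs hold 2 libraries of one label. No biological explanation was tested, and until the sample map is checked a difference between labels is one between libraries labelled so.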

How the results depend on the processing

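Of the alternatives, the fits of the 8 libraries labelled mock, HT-DNA, hpRNA and cGAMP, the blocks within 4 and 8 libraries and the split of the mock libraries were chosen after seeing the data. Calls against mock were 0 for HT-DNA, hpRNA and cGAMP, and 0 for HT-DNA against hpRNA, under each alternative run except DESeq2 (1 for HT-DNA and 1 for hpRNA) and the blocks. With the block within 4 libraries they were 6, 182, 6 and 11, and within the 8 libraries 14, 0, 23 and 25. In the fit of the 8 libraries without a block, 288, 238, 483 and 285 of 14543 genes had an unadjusted p under 0.05. HSV against G3-YSD had 1 without the filter, 1 with DESeq2 and 13 with the block within 4 libraries. Without the filter, where the balance of higher and lower turned in each, G3-YSD and HSV against mock had 1894 and 1892, cGAMP against G3-YSD 1650 and HSV against cGAMP 1633. With DESeq2 these were 2043, 2119, 1952 and 1927, and with only the 4 libraries compared 0 each. Leaving out 1 library gave 0 to 652 for G3-YSD, 0 to 682 for HSV, 0 to 567 for cGAMP against G3-YSD and 0 to 671 for HSV against cGAMP. The cause was not tested. The fit of 4 libraries and those without 1 library hold fewer samples. The fit of 4 libraries also takes its spread from those libraries alone. The fits without 1 library are of equal size and still ranged widely, so the number of samples alone does not account for their range. With the replicate number as a block over all 12 libraries the 4 counts were 1211, 1214, 1142 and 1079. Deviations of same-numbered libraries correlated between 0.32 and 0.59 among mock, HT-DNA, hpRNA and cGAMP, at 0.93 between G3-YSD and HSV, and between -0.33 and -0.29 across these sets, so the numbers do not pair all 12 samples but move together within each set. List tests called fell from 72 to 0 with an estimated correlation and were 64 with the block, and the median, mean and direction of a list did not share a sign in 28 of 171 tests. The overlap of G3-YSD and HSV fell from 766 to 471 at 2-fold or more, and to 0 with the mock libraries split either way, where each comparison had 0 calls. Interferon-stimulated genes called higher were 0 in each setting run, except with the block within 4 libraries (2 each for HT-DNA, cGAMP and HT-DNA against hpRNA) and within the 8 libraries (4, 4 and 5). Of 174 called values of named genes, 168 kept their call with RLE, 148 with upper quartile, 151 without the filter, 174 with DESeq2 and 164 with the block, but 0 of 173 with only the 4 libraries compared, 0 of 94 without mock 1 or mock 2, 0 of 80 without cGAMP 1 or cGAMP 2, 50 of 87 without G3-YSD 1, 17 without G3-YSD 2, 58 without HSV 1 and 21 without HSV 2. Of these 0 were reversed.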

Other observations

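The tests of depth, of genomic DNA in G3-YSD 2 and HSV 2, of positions from 10 to 50 kb in G3-YSD 1 and HSV 1, and of the position of genes called higher were chosen only after the result was seen. The even-spread test and the tests from 10 to 50 kb in G3-YSD 2 and HSV 2 were set before their own values were computed, but once the shares near and far from expressed genes were known.

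Cytosolic ribosomal protein genes summed to 72139 CPM in G3-YSD 2 and 69715 CPM in HSV 2, against 54659.5 CPM in G3-YSD 1 and 56619 CPM in HSV 1. Mitochondrial genes took 3.64% and 3.53% of counts in G3-YSD 2 and HSV 2. Replication-dependent histones summed to 308 CPM in G3-YSD 1 and 288 CPM in HSV 1, against 90.3 and 93.1 CPM in G3-YSD 2 and HSV 2. Markers of other cell types summed to between 113 and 141 CPM in the 12 libraries, with a median log2 fold change per gene of 1.04 in G3-YSD and 0.96 in HSV against mock.

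G3-YSD 1 and HSV 1 detected more genes than the other libraries. Library depth is argued against, since at equal depth they still detected at least 3861 genes more than the highest of the 8 libraries labelled mock, HT-DNA, hpRNA and cGAMP. Transcription running past gene ends stays open, since the share detected within 10 kb on the 3' side was at most 0.70 times that on the 5' side but rests on 4 and 6 genes, and from 10 to 50 kb it was 1.17 and 1.14 times that share, on 33 and 32 genes, with exact odds ratio intervals of 0.694 to 2.00 and 0.670 to 1.95 that reach past the ratio of 1.5 set for it. Genomic DNA in the RNA stays open as well: within 10 kb the 3' share was at most 1.33 times the far share, but from 10 to 50 kb it was 1.79 and 1.92 times that share (2.64% and 2.56% against 1.48% and 1.33%), with intervals that do not overlap, and the 5' share was nearly as high at 2.25% in both, so the excess was not particular to the 3' side. Spread evenly over exons, it would give close to the simulated 99.2% of the expected far genes with a count, which was not met at 49.97% and 50.8% (74.3% and 74.1% in G3-YSD 2 and HSV 2), but the bound set for excluding it was not met in both libraries and uneven coverage was not tested, nor was any other biological explanation.

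In G3-YSD 2 and HSV 2 silent genes were detected more often on the 3' side of expressed genes than on the 5' side. Within 10 kb, 7.99% of 338 silent genes were detected in G3-YSD 2 and 9.47% in HSV 2, against 1.17% and 0.97% of 514 on the 5' side. Genomic DNA in the RNA is argued against, since the 3' share was at least 36.6 times the share far away. Longer 3' ends than annotated are argued against by a ratio of the 3' to the 5' share of at least 6.86 from 10 to 50 kb. Transcription running past gene ends may account for it, as a hypothesis, on the same value of 6.86. The prediction for this hypothesis also held that the 3' share falls with distance. From 10 to 50 kb that share was 6.00% (4.75 to 7.46) in G3-YSD 2 and 6.48% (5.18 to 7.99) in HSV 2. These intervals overlap those within 10 kb, so a fall was not shown. No other biological explanation was tested.

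Genes with a mean under 1 CPM in the 8 libraries that were called higher were compared by position with the other tested genes of that level. The comparison could not decide whether they lie more often on the 3' side. Both sets had passed the filter on low counts, which a gene can pass through its level in G3-YSD or HSV libraries alone. In G3-YSD against mock 27 lay on the 3' side and 12 on the 5' side within 50 kb, against 640 and 400 of the rest (two-sided Fisher's exact p = 0.402, adjusted over 2 tests 0.402). In HSV against mock the counts were 31 and 10 against 636 and 402 (p = 0.0718, adjusted 0.144, Fisher's exact).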
